A study of Mus musculus with 2 samples.

How the data were processed

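The series measured messenger RNA by sequencing in mouse embryonic stem cells (wild type, mixed 129Sv and C57Bl/6 strain, total RNA, libraries made with a standard Illumina protocol). It has 2 samples, DMSO and ICRF-193 (500 nM, 16 h), each labelled as 3 replicates. The single deposited file is a table of the comparison made by the authors, with no column per replicate. Per the submitters' processing notes the tools were TopHat, HTSeq and DESeq with the mouse genome build mm9; versions, annotation, settings and the strand of the kit are not stated.

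The deposited group columns hold a signal, the mean of reads per gene divided by a size factor per library, as the authors normalised them. The deposited foldChange column is a ratio, the ICRF-193 mean over the DMSO mean, and the deposited log2FoldChange column is its log2 without shrinkage. The deposited p-values are those of the authors' test per gene, before and after adjustment for multiple testing. Recomputed on the file, the ratio differed from that of the group means by at most 1.15e-14 and the adjusted p from the Benjamini-Hochberg adjustment by at most 2.59e-15. The table holds 21937 genes, of which 18759 have reads and 3178 have none. Counts of genes that rose or fell use the authors' deposited table, at an adjusted p under 0.05 over the 18759 genes.

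The plan, made before the data were examined, took a count test on counts per replicate, or the deposited test where only a table of the comparison was given; the latter applied, so the deposited test is the main result. Each group column is given to 15 significant digits and is a sum of whole reads of 3 libraries, each with its own step. The whole reads per library were therefore recovered from the digits by a lattice search for all combinations of 3 whole numbers that give the printed mean. A gene was taken where a single combination fitted, or where one had a posterior of at least 0.99 under the spread between libraries (prior with 3 degrees of freedom). This gave 17921 genes with a single solution (95.5%) and 806 by posterior, while 32 genes of high level stayed unresolved, Mdm2, Ncl, Rpl4, Rpl8, Atp5a1 and Atp5b among those named; these have no standard deviation. All 16787 genes with both means below 5000 had a single solution. Size factors recomputed from the recovered reads differed from the steps by at most 0.0114%. In simulated reads all 6127 genes with a single solution and all 501 resolved by posterior were recovered exactly. The simulated genes of high level were scaled up from genes in the range where the prior was learned. Whether the 806 real genes share that spread was therefore not tested. The step gives no replicate number, so libraries were named A, B and C within each group by decreasing size factor. This recovery and the tests on it were chosen after the deposited values were seen.

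Recovered reads were compared with limma-voom (limma 3.58.1, R 4.3.3) on genes with at least 10 reads in at least 3 libraries, with the size factors worked back with the reads, the group as the main term, and Benjamini-Hochberg adjustment over 14995 genes. A further fit added a term for the split of the libraries into the 2 libraries A and the 4 libraries B and C. In the simulation, in which 200 genes were changed, the group fit found 0 of 67 genes changed by 0.5 on the log2 scale, 9 of 67 by 1 and 54 of 66 by 2, with 0 false calls. The fit with the split term found 40 of 67, 63 of 67 and 66 of 66, with 10 false calls. The simulation gave libraries A the same shift per gene in both groups, which is what the split term assumes. It therefore cannot show how many false calls that fit makes where this does not hold. Values ± SD are means and standard deviations of normalised reads over the 3 recovered libraries of a group. Depth ran from 29501258 to 47454467 recovered reads per library, and counting error of the reads is part of the spread between libraries.

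A total of 40 gene lists were fixed before the data were examined: topoisomerases, p53 targets, naive and core pluripotency, primed epiblast, primitive and visceral endoderm, trophectoderm, mesoderm and primitive streak, definitive endoderm, neuroectoderm and neurons, Hox genes, germline, 2-cell embryo, imprinted, G2 and mitosis, G1/S and replication, cell cycle inhibitors, DNA damage response and repair, condensin, cohesin and SMC, histone, Polycomb and trithorax, chromatin remodellers, immediate early, apoptosis, unfolded protein and integrated stress response, heat shock, glycolysis and hypoxia, cholesterol, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis and MYC targets, Wnt targets, TGF-beta, Nodal and BMP, FGF and ERK, Notch, interferon, fibroblast and feeder cells, actin cytoskeleton, long neuronal, mitochondrially encoded and housekeeping genes. Older and newer symbols were matched through the annotation. For each list the members that rose or fell were counted over all genes and adjusted over the list alone. The median of the deposited log2 fold change of members at a mean level of 10 or more was compared, two-sided, with 10000 random lists of the same size matched on mean level in 20 bins, and called members were compared with all genes by Fisher's exact test, both adjusted over 39 lists. On the recovered reads camera was run with a preset correlation of 0.01 and with an estimated correlation, and with fry. In simulated values the random list test passed 6 of 100 unchanged lists and 45 of 50 lists shifted by 0.5 on the log2 scale. These values were independent between genes. The correlation estimated between ribosomal protein genes was 0.87 in the group fit, whose residuals hold the split of the libraries, and 0.10 with the split term. Adjusted p-values given below with an estimated correlation are from the group fit unless the split term is named. The simulation therefore does not show how often this test passes unchanged lists of correlated members.

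Genes were named by a rule: all topoisomerases at a mean level of 10 or more; the 12 largest rises and 12 largest falls with an adjusted p under 0.05 and a level of at least 50 in the higher group, leaving out clone names; and from each list up to 4 called members with the smallest adjusted p, or 2 of the highest level where none was called; not all genes so chosen are given in the text. Genes named outside the rule are given as such. Gene span, exonic length, GC content and chromosome order came from a newer mouse annotation (GENCODE M21 on GRCm38) by symbol, for 18462 genes, since the annotation of the authors is not stated; no coordinates are given. Relations with length and level are Spearman's rho across genes, and neighbours were compared with 1000 permutations of gene order within the genome.

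The alternatives were other thresholds (adjusted p 0.1 and 0.01, Bonferroni, absolute log2 fold change of 0.58 and 1, mean level of 10 and 100), recentring, pseudocounts of 1 and 10, and the limma-voom fits with upper quartile or total read scaling, without a filter, without each library, without both libraries A, and with a term for library pairs. A fit without 1 library and without the split term gives libraries A unequal weight in the 2 groups. Its medians can therefore shift for lists that differ between libraries A and the rest. Another 6 lists were chosen after values were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes without reads in either group were left out of all tests, and genes with reads in 1 group only were left out of relations of the log2 fold change, which is infinite for them.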

Results

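Messenger RNA was sequenced from wild-type mouse embryonic stem (ES) cells grown without feeder cells and treated for 16 h with 500 nM ICRF-193 or with its solvent DMSO. ICRF-193 is a catalytic inhibitor of topoisomerase II, the enzyme that untangles DNA by passing 1 duplex through another. Each of the 2 groups held 3 libraries. The deposited table gives the mean of each group in normalised reads per gene (reads divided by a size factor per library), with the fold change and p-value of the authors' DESeq test. Reads per library were worked back from these means, and the libraries were named A, B and C within each group by decreasing size factor, which is a name and not a replicate number. The recovered totals were 47454467, 36785748 and 33551865 reads for DMSO-A, DMSO-B and DMSO-C. They were 34208398, 32111452 and 29501258 reads for ICRF-193-A, ICRF-193-B and ICRF-193-C. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which can be technical.

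Libraries A of both groups stood apart from libraries B and C. Col1a1, which encodes type I collagen, was at 12908 normalised reads in DMSO-A against 923 and 874 in DMSO-B and DMSO-C, and at 15180 in ICRF-193-A against 1907 and 1323. Zscan4a, a gene of the 2-cell embryo with near-identical copies, was at 233 in DMSO-A against 17.9 and 43.2, and at 383 in ICRF-193-A against 42.5 and 56.1. Gata6, an endoderm transcription factor, was at 411 in DMSO-A against 51.6 and 111, and at 476 in ICRF-193-A against 125 and 219. The ratio of library A to B and C also increased with the exonic length of the gene, with Spearman's rho across 11707 genes of 0.618 in DMSO and 0.592 in ICRF-193; genes are not independent replicates. Beyond counting error, B and C differed by a coefficient of variation of 6.74% in DMSO and 7.05% in ICRF-193, and A differed from them by 23.1% to 27.2%. Results are therefore also given for pair A (ICRF-193-A over DMSO-A) and for pairs B and C.

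**Figure D1:**
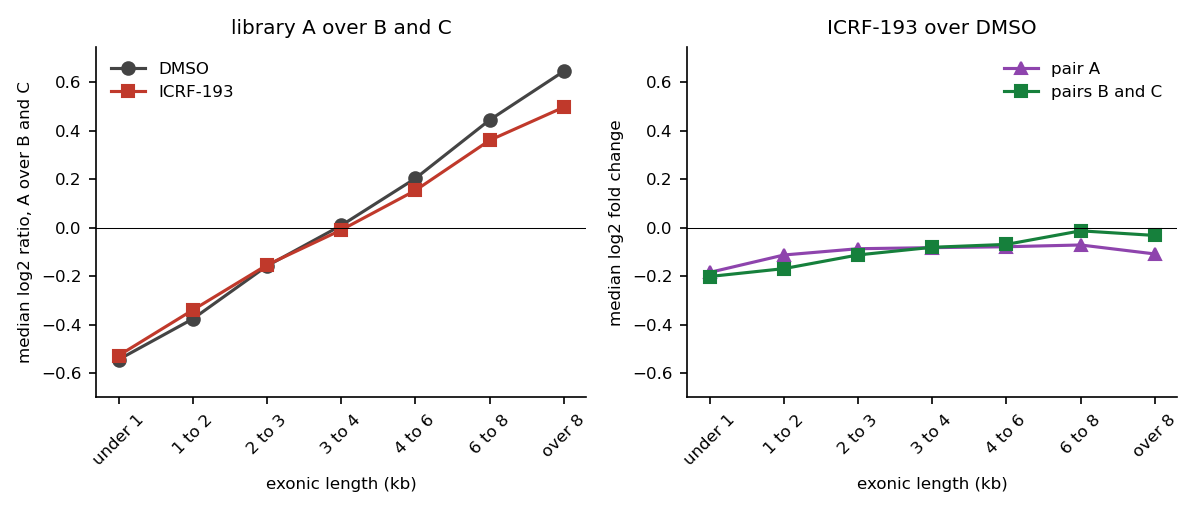
Median log2 ratio of library A to libraries B and C (y axis) by exonic gene length in kb (x axis), for DMSO and ICRF-193, over 11707 genes at a mean level of 100 normalised reads or more. The medians climb from -0.54 and -0.53 under 1 kb to 0.65 and 0.50 over 8 kb.

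The comparison asks how gene expression changed in ES cells when topoisomerase II was inhibited. After 16 h of ICRF-193, 24 of 41 targets of the tumour suppressor p53 were higher, led by Trp73, a relative of p53, which rose 11.3-fold. The largest rises, from few reads in DMSO, included the keratin genes Krt15 and Krt5, the integrin gene Itgb2 and the Wnt ligand gene Wnt8b. Of 24 genes of the unfolded protein and integrated stress response 14 fell, led by Chac1, an enzyme that degrades glutathione, which was 17.4-fold lower. Pluripotency genes such as Zfp42, Dppa3 and Fbxo15 fell to 0.504, 0.340 and 0.484 of their DMSO levels. By the test in the authors' deposited table, 1120 of 18759 genes with reads rose and 237 fell at an adjusted p under 0.05, so that 82.5% of the changed genes were higher.

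**Figure D2:**
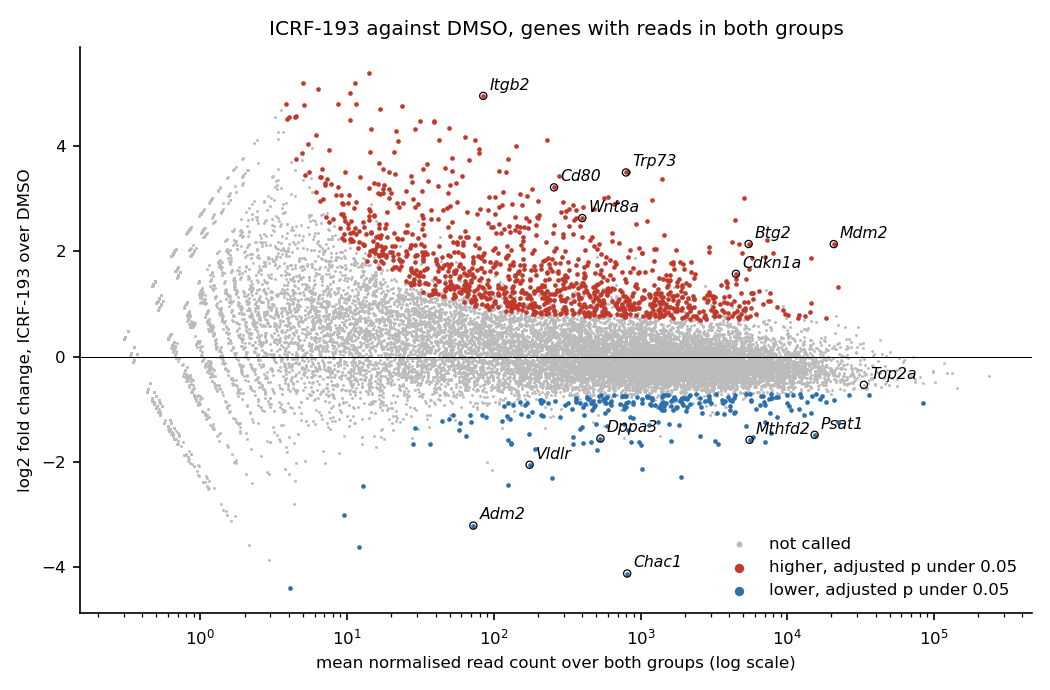
Deposited log2 fold change of ICRF-193 over DMSO (y axis) against mean normalised reads per gene (log10 x axis), one point per gene with reads in both groups, with the genes at an adjusted p under 0.05 coloured. The 1120 higher genes had a median level of 186 and the 237 lower genes one of 1157.

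The transcripts of the topoisomerases themselves come first, since the drug acts on the protein of Top2a and Top2b. Top2a, the form of dividing cells, was at 39346 ± 7092 to 27163 ± 5804 normalised reads, and Top2b, the form also found in resting cells, at 4376 ± 1109.7 to 4082 ± 1217 (mean ± SD, n = 3; DMSO to ICRF-193). Top1, which relaxes supercoils by cutting a single strand, was at 12932 ± 836 to 9121 ± 928, and Top3b at 4508 ± 259.9 to 6135 ± 466 (mean ± SD, n = 3). In the authors' deposited table the log2 fold changes were -0.53 for Top2a (adjusted p = 0.176), -0.10 for Top2b (adjusted p = 0.974), -0.50 for Top1 (adjusted p = 0.237) and 0.44 for Top3b (adjusted p = 0.341). Those of Top1mt, Top3a, Tdp1 and Tdp2 in the authors' deposited table lay between -0.31 and 0.34. The authors' DESeq test called 0 of the 9 genes, also 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05, both lower. On the recovered reads limma-voom called 2, Top1 lower and Top3b higher, and 7 with a term for the split of the libraries, 2 higher and 5 lower. Without DMSO-A or ICRF-193-A limma-voom called 3, and without any other single library 0. The list's median log2 fold change was -0.20 (-0.22 in pair A, -0.19 in pairs B and C; permutation test against random lists of similar level, adjusted p = 0.758).

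How many genes passed depended on how the libraries were modelled. On the recovered reads of 14995 genes limma-voom called 1461 genes higher and 892 lower. It shared 1014 of the 1085 deposited higher calls that it tested and 227 of the 235 lower ones. A term for the split between libraries A and the rest gave 4056 higher and 4895 lower, and leaving out both libraries A gave 3761 and 4322; each kept all 1085 and 235 deposited calls. The share of higher genes was 82.5% in the deposited test, 62.1% in limma-voom, 45.3% with the split term, and 63.6% with the split term and total read scaling. Both directions gained calls with the split term. Scaling by total reads moved the median of all genes in the limma-voom fit from -0.04 to 0.08 and the calls to 1845 higher and 407 lower. In limma-voom without the split term, the numbers also changed with single libraries. Without DMSO-B there were 476 higher and 109 lower, without DMSO-C 604 and 200, without ICRF-193-B 499 and 109, and without ICRF-193-C 549 and 139. Leaving out ICRF-193-A gave 1356 and 584, and leaving out DMSO-A gave 1719 and 1382. A limma-voom test of whether the treatment effect differed between libraries A and the rest called 0 of 14995 genes. Of these, 1157 were at an unadjusted p under 0.05, and the lowest adjusted p in this limma-voom test was 0.0727. Each group holds a single library A, so the test could miss real differences and does not show that the effect was equal.

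Targets of p53 rose in part. Of 41 measured members 24 rose and 17 did not pass; adjusted over the list alone 31 rose and 1, Rrm2b, fell. Trp73 rose from 129 ± 2.70 to 1461 ± 117 normalised reads, Cd80, a costimulatory surface protein, rose 9.28-fold to 464 ± 49.7, and Btg2, a growth inhibitor, rose from 2016 ± 377 to 8879 ± 1009 (mean ± SD, n = 3). Mdm2, the ubiquitin ligase that restrains p53, rose 4.40-fold from 7681 to 33782; its reads per library could not be resolved. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose from 2246 ± 901 to 6681 ± 599.9 (mean ± SD, n = 3). In the authors' deposited table the log2 fold changes were 3.50 for Trp73 (adjusted p = 5.93e-32), 3.21 for Cd80 (adjusted p = 4.01e-23), 2.14 for Btg2 (adjusted p = 2.12e-14), 2.14 for Mdm2 (adjusted p = 1.80e-14) and 1.57 for Cdkn1a (adjusted p = 8.56e-08). Chosen after their values were seen, the death genes Bax and Bbc3 did not pass in the authors' DESeq test: the deposited table gives 0.10 (adjusted p = 0.973) and 0.59 (adjusted p = 0.238). With the split term limma-voom called Bbc3 higher (adjusted p = 8.24e-05). Of the whole list limma-voom called 28 higher and 1 lower, and with the split term 36 higher and 1 lower. The transcript of p53 itself, Trp53, was at 16269.7 ± 1753 to 15391 ± 2164 normalised reads (mean ± SD, n = 3). The list's median log2 fold change was 0.99, 0.88 in pair A and 1.02 in pairs B and C (permutation test, adjusted p = 0.000867, from the smallest p that 10000 random lists can give; adjusted p = 0.0961 with an estimated correlation in camera).

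The unfolded protein and integrated stress response comprises 2 linked reactions to misfolded proteins and to missing amino acids. Of 24 members 14 fell, 2 rose and 8 did not pass, with the same numbers adjusted over the list alone. Chac1 fell from 1531 ± 337 to 88.3 ± 19.7 normalised reads and Vldlr, a lipoprotein receptor, from 282 ± 9.12 to 68.1 ± 20.5 (mean ± SD, n = 3). Mthfd2, a mitochondrial folate enzyme, fell from 8286 ± 694 to 2772 ± 215, and Psat1, an enzyme of serine synthesis, from 22623 ± 2358 to 8087 ± 1201 (mean ± SD, n = 3). The authors' deposited table gives log2 fold changes of -4.12 for Chac1 (adjusted p = 3.97e-21), -2.05 for Vldlr (adjusted p = 1.04e-09), -1.58 for Mthfd2 (adjusted p = 2.05e-08) and -1.48 for Psat1 (adjusted p = 1.59e-07). Also falling, and chosen after their values were seen, were Atf4, the transcription factor of this response, 2.72-fold, its target Trib3 2.47-fold, and asparagine synthetase, Asns, 1.85-fold. The pair that rose was Atf3 and Ddit4, which other stresses and p53 are also known to induce. Among those that did not pass were Hspa5, the main chaperone of the endoplasmic reticulum, and Xbp1, with deposited log2 fold changes of 0.24 and -0.25. The lower members exceeded their share among all genes (Fisher's exact test, adjusted p = 2.57e-18), and the list's median was -0.90, -0.87 in pair A and -0.99 in pairs B and C (permutation test, adjusted p = 0.000867). In camera on the recovered reads, with an estimated correlation, the adjusted p of the list was 0.333. The list's A to B and C log2 ratio was -0.30 in DMSO and -0.21 in ICRF-193.

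Some pluripotency genes fell, while the core factors passed only in fits on the recovered reads. Of 29 members of the naive and core pluripotency list 6 fell and 23 did not pass; adjusted over the list alone 11 fell. Zfp42, a marker of naive ES cells, fell from 8155 ± 1734 to 4111 ± 552 normalised reads, Dppa3 from 794 ± 218 to 270.4 ± 71.3, Fbxo15 from 5915 ± 419 to 2864 ± 445 and the growth factor gene Fgf4 from 4817 ± 496 to 2671 ± 385 (mean ± SD, n = 3). In the authors' deposited table their log2 fold changes were -0.99 (adjusted p = 0.00186), -1.55 (adjusted p = 0.0012), -1.05 (adjusted p = 6.37e-04) and -0.85 (adjusted p = 0.0086). The core factors Pou5f1, Sox2 and Nanog, chosen after their values were seen, did not pass in the authors' DESeq test: the deposited table gives -0.40 (adjusted p = 0.53), -0.66 (adjusted p = 0.0734) and -0.51 (adjusted p = 0.834). Each was lower in each of the 3 library pairs; limma-voom called Sox2 lower (adjusted p = 0.00878), and with the split term all 3 (adjusted p = 1.43e-04, 6.40e-06 and 0.00361). Of the whole list limma-voom called 7 lower, and with the split term 23 lower and 1 higher. The list's median was -0.55, -0.57 in pair A and -0.64 in pairs B and C (permutation test, adjusted p = 0.000867, and adjusted p = 0.28 with an estimated correlation in camera). Its A to B and C log2 ratio was 0.29 in DMSO and 0.28 in ICRF-193. Of 15 genes of the primed epiblast, the state after implantation, 4 fell, 1 rose and 10 did not pass, the same adjusted over the list alone. The fallen ones were the zinc finger genes Zic2 and Zic5, Foxd3 and the DNA methyltransferase gene Dnmt3b, and the risen one was Wnt8a. Zic2 fell from 1666 ± 298 to 378 ± 94.1, Zic5 from 416 ± 28.7 to 84.1 ± 18.1 and Foxd3 from 1193 ± 190.3 to 457 ± 104 normalised reads (mean ± SD, n = 3). The authors' deposited table gives -2.14 for Zic2 (adjusted p = 6.95e-13), -2.30 for Zic5 (adjusted p = 3.06e-13) and -1.38 for Foxd3 (adjusted p = 5.13e-06). This list's median was -0.55, -0.25 in pair A and -0.64 in pairs B and C, with an A to B and C log2 ratio of -0.57 in DMSO and -0.54 in ICRF-193 (permutation test, adjusted p = 0.000867; adjusted p = 0.591 with an estimated correlation).

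The 12 largest rises started from low levels, at most 25.2 normalised reads in DMSO. Itgb2, an integrin of white blood cells, rose from 5.31 ± 2.94 to 164 ± 24.8 normalised reads, C4b, a complement protein, from 3.34 ± 4.0 to 74.5 ± 8.59, with DMSO-A at 7.96 against 0.992 and 1.08 in DMSO-B and DMSO-C, and Sec14l3 from 2.68 ± 1.47 to 59.6 ± 0.832 (mean ± SD, n = 3). Of epithelial genes, Krt15 rose from 3.4 ± 0.520 to 74.5 ± 13.7, Trim29 from 4.69 ± 0.328 to 94.5 ± 16.3 and Krt5 from 4.65 ± 2.76 to 80.0 ± 31.9 (mean ± SD, n = 3). In the authors' deposited table the log2 fold changes were 4.95 for Itgb2 (adjusted p = 2.68e-27), 4.45 for Krt15 (adjusted p = 5.39e-15) and 4.33 for Trim29 (adjusted p = 2.69e-17). Wnt8b rose 19.9-fold, Them5 17.9-fold, Fbp1, an enzyme of glucose synthesis, 17.3-fold, and Cbln2 15.3-fold. Ltb4r2 and Ltb4r1, receptors for leukotriene B4, rose 17.3-fold and 15.9-fold; they overlap on the genome and the strand of the kit is not stated, so their reads cannot be assigned with certainty. Of the 12 largest falls, Chac1, Vldlr and Herpud1 are members of the unfolded protein and integrated stress response list. After Chac1 the largest were Adm2, a peptide hormone gene, 9.23-fold, Zic5 4.94-fold, Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, 4.85-fold, and Zic2 4.41-fold. Vldlr fell 4.15-fold, Stc2 3.42-fold, Glod5 3.39-fold, Herpud1, a gene of protein degradation at the endoplasmic reticulum, 3.18-fold, and Aldh18a1, an enzyme of proline synthesis, 3.17-fold. Neurog3, a transcription factor of endocrine cells, fell 3.16-fold and Klf15 3.16-fold.

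**Figure D3:**
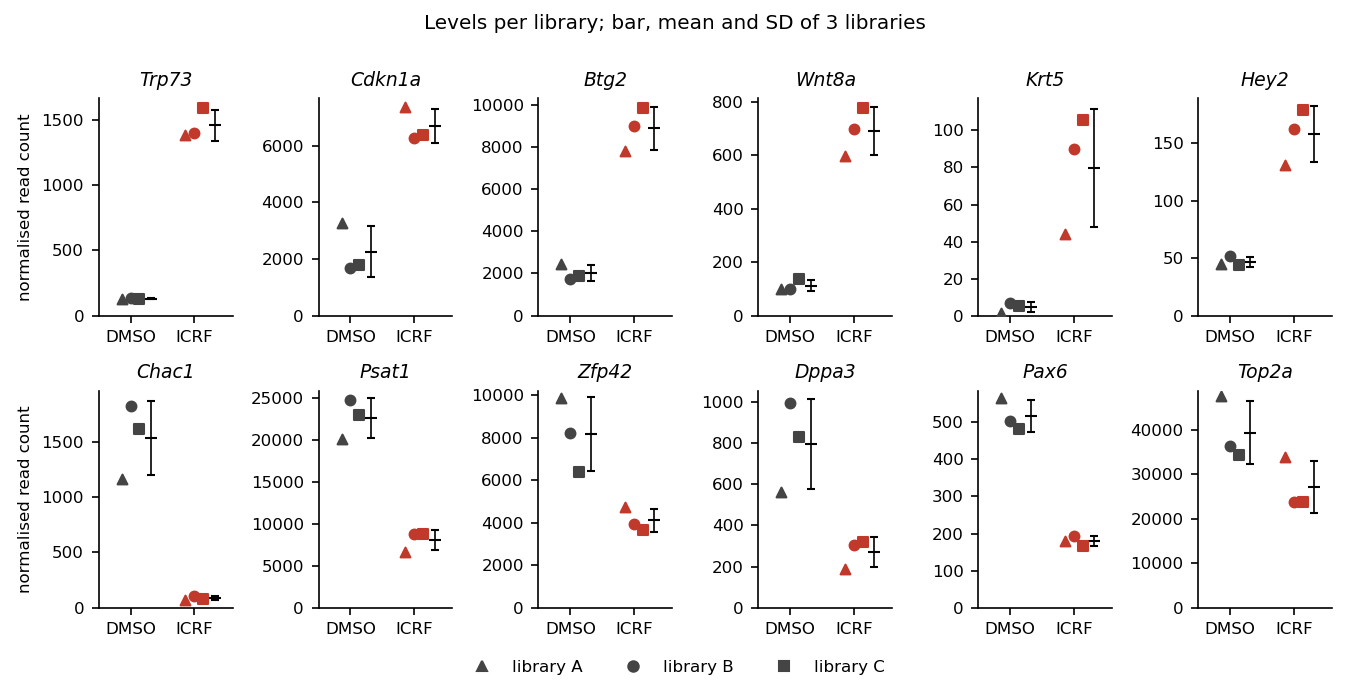
Normalised reads per library (y axis) of named genes in the 3 DMSO and 3 ICRF-193 libraries, one point per library with A, B and C marked and a bar at the group mean and SD. Trp73 went from a mean of 129 to 1461 and Chac1 from 1531 to 88.3 normalised reads.

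Lineage genes rose singly, and few lists passed as a whole. Of 20 trophectoderm genes 3 rose and 17 did not pass (4 rose adjusted over the list alone): Dlx3 from 97.0 ± 13.7 to 347 ± 51.6 normalised reads, 1600029D21Rik from 247 ± 12.1 to 580.2 ± 82.6, and the keratin gene Krt18 from 9751 ± 560.0 to 16626 ± 3318 (mean ± SD, n = 3). Limma-voom called 3 trophectoderm genes higher, and 13 with the split term. That list's median was 0.71, 0.45 in pair A and 0.77 in pairs B and C (permutation test, adjusted p = 0.00167, and adjusted p = 0.333 with an estimated correlation in camera). Of 24 genes of mesoderm and primitive streak 4 rose and 20 did not pass (5 rose adjusted over the list alone). They were Wnt3, a signal that starts the streak, from 192 ± 48.4 to 850.2 ± 108, Wnt3a from 30.3 ± 8.56 to 127 ± 11.5, Meox1 from 26 ± 0.999 to 75.2 ± 11.6 and Mesp2 from 77.5 ± 6.17 to 159 ± 10.3 (mean ± SD, n = 3). The mesoderm median of 0.63 did not pass against random lists (permutation test, adjusted p = 0.133), but passed among members at a level of 100 or more (0.76) and without ICRF-193-B (0.75) or ICRF-193-C (0.83). Among 36 genes of neuroectoderm and neurons 7 rose, 1 fell and 28 did not pass; adjusted over the list alone 7 rose and 3 fell. The fallen one was Pax6, a regulator of eye and brain, from 516 ± 42.8 to 179.5 ± 13.4 normalised reads, while Nkx2-2 rose from 2.66 ± 2.39 to 20.5 ± 3.26 and Neurod1 from 1187 ± 516 to 3063 ± 804 (mean ± SD, n = 3). Neurod1 did not pass in limma-voom (adjusted p = 0.0534). Neurog2 rose from 0.626 ± 0.560 to 20.2 ± 11.6 (mean ± SD, n = 3), on so few DMSO reads that no fold is given. The neural median was 0.37 (permutation test, adjusted p = 0.133) and passed without DMSO-B (0.40), with a pseudocount of 10 (0.36), and on the recovered reads with upper quartile (0.49) or total read scaling (0.55). Definitive endoderm genes gave 0 calls of 12 in the authors' DESeq test, 0 adjusted over the list alone and 3 higher at an unadjusted p under 0.05; limma-voom called 2 higher, and 4 with the split term. Its most abundant members were Tspan7, listed as Tm4sf2, at 1669 ± 620.4 to 1739 ± 659 normalised reads and Hhex at 274 ± 10.1 to 397 ± 25.3 (mean ± SD, n = 3), and its median was 0.42 (permutation test, adjusted p = 0.638).

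The next 5 lists differed between libraries A and the rest, and few of their members passed. A fit without 1 library gives libraries A unequal weight in the 2 groups. The medians of such lists then shift with their A to B and C ratio, whatever the treatment did. Of 22 genes of primitive and visceral endoderm 1 rose, Cited1, from 94.3 ± 5.59 to 181 ± 16.3 normalised reads (mean ± SD, n = 3), with 1 adjusted over the list alone. The endoderm median of the A to B and C log2 ratio was 1.80 in DMSO and 1.21 in ICRF-193. Its median log2 fold change was 0.25, 0.05 in pair A and 0.54 in pairs B and C (permutation test, adjusted p = 0.102), and it passed on the recovered reads (0.37), also without DMSO-A (0.94), ICRF-193-B (0.62) or ICRF-193-C (0.53). Of 39 Hox genes 1 rose, Hoxc13, from 72.7 ± 33.6 to 220.3 ± 7.51 (mean ± SD, n = 3), also 1 adjusted over the list alone. The Hox median was 0.14 (permutation test, adjusted p = 0.291) and passed below random lists without ICRF-193-A (-0.12), against an A to B and C log2 ratio of 1.20 in DMSO and 0.95 in ICRF-193. Among 19 genes of the 2-cell embryo the authors' DESeq test called 0, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05; limma-voom called 1 lower, Eif1a, and with the split term 8 higher and 1 lower. Zscan4a was at 98.1 ± 118 to 161 ± 193.03 normalised reads and Eif1a at 11395 ± 458 to 8666 ± 11.1 (mean ± SD, n = 3). Eif1a did not share the pattern of the list: its A to B and C log2 ratio was -0.098 in DMSO and -0.00078 in ICRF-193. That of Zscan4a was 2.89 and 2.93. The 2-cell median was 0.71 (permutation test, adjusted p = 0.181) and passed without DMSO-A (1.82), ICRF-193-B (1.26) or ICRF-193-C (1.18); its A to B and C log2 ratio was 2.89 in DMSO and 2.58 in ICRF-193. Of 23 fibroblast and feeder cell markers 2 rose and 21 did not pass (3 rose adjusted over the list alone). They were Col6a2, from 124 ± 5.89 to 237 ± 58.8, and the calcium-binding protein gene S100a6, from 4130.3 ± 265 to 7046 ± 1287 (mean ± SD, n = 3). The fibroblast median was 0.43, 0.38 in pair A and 0.52 in pairs B and C, with an A to B and C log2 ratio of 1.20 in DMSO and 0.88 in ICRF-193 (permutation test, adjusted p = 0.00877; adjusted p = 0.532 with an estimated correlation). It no longer passed without DMSO-B (0.16), DMSO-C (0.27) or ICRF-193-A (0.05), fits in which libraries A weigh more in DMSO. With the split term the fibroblast median was 0.44, with 14 members higher and 0 lower. Of 20 germline genes 2 rose, Taf7l from 115 ± 27.0 to 245 ± 23.8 and Tktl1 from 14.2 ± 9.92 to 44.4 ± 12.6 (mean ± SD, n = 3; Tktl1 in limma-voom, adjusted p = 0.0722), the same adjusted over the list alone, with a median of 0.06 (permutation test, adjusted p = 0.923) and an A to B and C log2 ratio of 0.55 in DMSO and 0.40 in ICRF-193. Of 28 imprinted genes 1 rose, Slc22a18, from 119 ± 9.32 to 237 ± 53.9 (mean ± SD, n = 3), also 1 adjusted over the list alone. The imprinted median of 0.16 lay above random lists (permutation test, adjusted p = 0.0186; adjusted p = 0.532 with an estimated correlation), but no longer without DMSO-A (0.12), DMSO-C (0.10), ICRF-193-A (0.06) or both libraries A (0.12).

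Single genes of several signalling pathways rose. Of 14 Notch targets 6 rose and 8 did not pass; adjusted over the list alone 7 rose and 2 fell. Hey2, a repressor induced by Notch, rose from 46.8 ± 4.13 to 158 ± 24.4 normalised reads, Notch3, a receptor, from 4549 ± 965 to 9134 ± 863, Heyl from 4.80 ± 3.23 to 24.3 ± 6.89 and the feedback inhibitor gene Nrarp from 332 ± 52.9 to 785 ± 239 (mean ± SD, n = 3). The higher Notch members exceeded their share among all genes (Fisher's exact test, adjusted p = 0.00475). In camera with an estimated correlation, a test on the recovered reads, the adjusted p of all Notch members was 0.452. Their median of 0.36 (0.42 in pair A, 0.39 in pairs B and C) did not pass (permutation test, adjusted p = 0.107), except among members at a level of 100 or more (0.54) and without DMSO-C (0.55) or ICRF-193-A (0.57). Of 18 Wnt targets 2 rose and 16 did not pass (4 rose adjusted over the list alone): Wnt8a, a Wnt ligand of the early embryo, from 111 ± 20.6 to 689.8 ± 89.3, and Sp5 from 349.6 ± 105 to 605 ± 102 (mean ± SD, n = 3). Sp5 did not pass in limma-voom (adjusted p = 0.0597). The Wnt median was 0.37, 0.46 in pair A and 0.32 in pairs B and C (permutation test, adjusted p = 0.0308; adjusted p = 0.31 with an estimated correlation). It no longer passed at a level of 100 or more (0.33), on the recovered reads (0.35), without both libraries A (0.32), or without DMSO-B (0.32), DMSO-C (0.33) or ICRF-193-A (0.32). Of 22 targets of TGF-beta, Nodal and BMP 2 rose, the same adjusted over the list alone: Nodal, a signal of the early embryo, from 2467 ± 331 to 5513 ± 398, and Id1, a target of BMP, from 3553 ± 533 to 7273 ± 789 (mean ± SD, n = 3). This median was 0.31, 0.33 in pair A and 0.31 in pairs B and C, with an A to B and C log2 ratio of 0.42 in DMSO and 0.49 in ICRF-193 (permutation test, adjusted p = 0.0013; adjusted p = 0.532 with an estimated correlation); it no longer passed without ICRF-193-A (-0.01). Of 15 FGF and ERK targets 1 fell, Fgf4, and 14 did not pass, the same adjusted over the list alone. The FGF median was 0.20 and its mean 0.00, with medians of 0.22 in pair A and 0.00 in pairs B and C (permutation test, adjusted p = 0.000867; adjusted p = 0.976 with an estimated correlation). It no longer passed without DMSO-B (0.02), DMSO-C (0.02), ICRF-193-A (-0.23) or both libraries A (0.00). Of 26 immediate early genes 4 rose and 22 did not pass (8 rose adjusted over the list alone). Fosl1, a subunit of AP-1, rose from 23.9 ± 2.06 to 208 ± 19.7, Dusp2, a phosphatase of MAP kinases, from 124 ± 52.2 to 348 ± 105, Atf3 from 340.0 ± 62.7 to 617 ± 132 and Jun from 1049 ± 174 to 1783 ± 73.3 (mean ± SD, n = 3). Their median was 0.40, 0.54 in pair A and 0.48 in pairs B and C (permutation test, adjusted p = 0.000867; adjusted p = 0.192 with an estimated correlation). Of 26 interferon-stimulated genes 2 rose, Irf7 from 2.47 ± 1.28 to 16.2 ± 3.63 and Usp18 from 3.81 ± 2.65 to 19.2 ± 6.69 (mean ± SD, n = 3), and 5 adjusted over the list alone. The interferon median was 0.21, with an A to B and C log2 ratio of -0.42 in DMSO and -0.48 in ICRF-193 (permutation test, adjusted p = 0.373), and passed without DMSO-B (0.41) or ICRF-193-A (0.50). Of 26 genes of the actin cytoskeleton 1 rose, Anxa1, from 2641 ± 764 to 4766 ± 823 (mean ± SD, n = 3), also 1 adjusted over the list alone. Their median was 0.35, 0.37 in pair A and 0.32 in pairs B and C, with an A to B and C log2 ratio of 0.28 in DMSO and 0.46 in ICRF-193 (permutation test, adjusted p = 0.000867; adjusted p = 0.618 with an estimated correlation).

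Inhibitors of the cell cycle moved both ways. Of 16 members 2 rose, 2 fell and 12 did not pass; adjusted over the list alone 5 rose and 2 fell. Beside Cdkn1a, the retinoblastoma gene Rb1 rose from 802 ± 236 to 2352 ± 380.3 normalised reads, while its relative Rbl1 fell from 1023 ± 163 to 513 ± 59.7 and Cdkn1b, which encodes the inhibitor p27, from 1928 ± 436 to 955 ± 218 (mean ± SD, n = 3). The median of the list was 0.34, 0.46 in pair A and 0.26 in pairs B and C (permutation test, adjusted p = 0.0101; adjusted p = 0.452 with an estimated correlation). It no longer passed without DMSO-A (0.10), ICRF-193-C (0.18) or both libraries A (0.24). Of 45 genes of G2 and mitosis 1 rose, Ckap2, a spindle protein gene, from 4966 ± 182 to 10289 ± 668, 1 fell, the mitotic kinase gene Plk1, from 8980.2 ± 931 to 4969.8 ± 317 (mean ± SD, n = 3), and 43 did not pass, the same adjusted over the list alone. On the recovered reads limma-voom called 1 of the G2 and mitosis genes higher and 9 lower, and with the split term 2 higher and 33 lower. Of the 45, 5 had a deposited log2 fold change above 0. The G2 median was -0.23, against -0.18 in random lists of similar level (permutation test, adjusted p = 0.417), and it passed without ICRF-193-C (-0.28). Of 35 genes of G1/S and replication the authors' DESeq test called 0, with 0 adjusted over the list alone and 2 lower at an unadjusted p under 0.05; limma-voom called 2 lower, and with the split term 3 higher and 16 lower. Mcm5 and Mcm3, subunits of the replicative helicase, were at 24309.5 ± 1629.9 to 22897 ± 1454 and 23278 ± 732 to 20112 ± 423 normalised reads (mean ± SD, n = 3), and the G1/S median was -0.13, or 0.02 when libraries were scaled by total reads (permutation test, adjusted p = 0.556). Of 26 apoptosis genes 2 rose, the same adjusted over the list alone: Pmaip1, which encodes the death protein NOXA, from 5859 ± 921 to 11224 ± 648, and Apaf1, a scaffold of caspase activation, from 2488 ± 1014 to 6494 ± 1283 (mean ± SD, n = 3). Their median was 0.01 (permutation test, adjusted p = 0.365). Of 32 genes of DNA damage response and repair the authors' DESeq test called 0, with 0 adjusted over the list alone and 3 lower at an unadjusted p under 0.05; limma-voom called 5 lower, and 18 with the split term. Parp1, a sensor of DNA breaks, was at 33133 ± 3824 to 23314 ± 1745 normalised reads (mean ± SD, n = 3), and the repair median was -0.14 (permutation test, adjusted p = 0.944).

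Chromatin lists had medians below 0 and few calls. Random lists of similar level also had medians below 0 for Polycomb and trithorax (-0.15), condensin, cohesin and SMC (-0.18) and remodellers (-0.18). For histones the random median was 0.10. Of 37 histone genes 1 fell, H1f0, a linker histone of resting cells, from 3540.1 ± 428 to 1684 ± 83.1 normalised reads (mean ± SD, n = 3), also 1 adjusted over the list alone. The histone median was -0.44, -0.45 in pair A and -0.45 in pairs B and C (permutation test, adjusted p = 0.000867; adjusted p = 0.413 with an estimated correlation); among members at a level of 100 or more it was -0.28 and did not pass. Of 30 Polycomb and trithorax genes the authors' DESeq test called 0, with 0 adjusted over the list alone and 3 lower at an unadjusted p under 0.05; limma-voom called 9 lower, and with the split term 1 higher and 21 lower. Phc1 and Jarid2, subunits of the Polycomb complexes, were at 34336 ± 1514 to 22743 ± 1503 and 27761 ± 4951 to 18093 ± 2431 (mean ± SD, n = 3). The Polycomb median was -0.38, -0.40 in pair A and -0.36 in pairs B and C (permutation test, adjusted p = 0.0013; adjusted p = 0.28 with an estimated correlation). Of 22 condensin, cohesin and SMC genes the authors' DESeq test called 0, with 0 adjusted over the list alone and 1 lower at an unadjusted p under 0.05; limma-voom called 3 lower, and 21 with the split term. Ncapd2 of condensin was at 18090.3 ± 1913 to 14342 ± 1249.9 and Rad21 of cohesin at 16265 ± 1808 to 12413 ± 1770.3 (mean ± SD, n = 3). Their median of -0.27, with an A to B and C log2 ratio of 0.41 in DMSO and 0.34 in ICRF-193, did not pass (permutation test, adjusted p = 0.187), except without DMSO-B (-0.32), DMSO-C (-0.37) or ICRF-193-A (-0.41). Among 26 chromatin remodellers 1 fell, Ino80, an ATPase that moves nucleosomes, from 4030.1 ± 610.2 to 2481 ± 239 (mean ± SD, n = 3), and 0 passed adjusted over the list alone. The remodeller median was -0.19, with an A to B and C log2 ratio of 0.40 in DMSO and 0.38 in ICRF-193 (permutation test, adjusted p = 0.884), and it passed without ICRF-193-A (-0.34).

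Of 26 genes of glycolysis and hypoxia 5 fell and 21 did not pass; adjusted over the list alone 9 fell. Bnip3, a mitophagy gene induced by hypoxia, fell from 836 ± 106 to 336 ± 13.6 normalised reads, Vegfa, the vascular growth factor gene, from 2191 ± 135 to 1249.7 ± 111, and Pfkp, a phosphofructokinase, from 5466 ± 1502 to 2723 ± 445 (mean ± SD, n = 3). Eno1 fell from 178 ± 8.25 to 78.8 ± 15.2 (mean ± SD, n = 3), a low level for this enzyme, and reads shared with its retrocopies cannot be assigned with certainty. The glycolysis median was -0.52, -0.67 in pair A and -0.54 in pairs B and C (permutation test, adjusted p = 0.000867; adjusted p = 0.0961 with an estimated correlation). Of 28 genes of ribosome biogenesis the authors' DESeq test called 0, with 0 adjusted over the list alone and 10 lower at an unadjusted p under 0.05; limma-voom called 9 lower, and with the split term 1 higher and 23 lower. Ncl, a nucleolar protein, went from 172056 to 114019.9 normalised reads. The biogenesis median was -0.40, -0.35 in pair A and -0.42 in pairs B and C, with an A to B and C log2 ratio of -0.25 in DMSO and -0.21 in ICRF-193 (permutation test, adjusted p = 0.0013; adjusted p = 0.333 with an estimated correlation). Of 38 ribosomal protein genes the authors' DESeq test called 0, with 0 adjusted over the list alone and 3 lower at an unadjusted p under 0.05; limma-voom called 0, and 30 lower with the split term. Rpl4 was at 107141 to 88395 and Rpl8 at 84980.0 to 63013 normalised reads. The ribosomal median was -0.34, -0.33 in pair A and -0.32 in pairs B and C (permutation test, adjusted p = 0.00167, and adjusted p = 0.64 with an estimated correlation in camera). The list's A to B and C log2 ratio was -0.58 in DMSO and -0.62 in ICRF-193. The median no longer passed without DMSO-B (-0.22), DMSO-C (-0.26) or ICRF-193-A (-0.13), fits in which libraries A weigh more in DMSO. With the split term it was -0.35. Of 22 cholesterol genes the authors' DESeq test called 0, with 0 adjusted over the list alone and 1 lower at an unadjusted p under 0.05; limma-voom called 3 lower, and 11 with the split term. The cholesterol median was -0.18 (permutation test, adjusted p = 0.512). Of 29 genes of oxidative phosphorylation the authors' DESeq test called 0, with 0 adjusted over the list alone and 1 lower at an unadjusted p under 0.05; limma-voom called 1 lower, and 16 with the split term. Atp5b, a subunit of ATP synthase, was at 97941 to 69631 normalised reads, and the list's median was -0.19 (permutation test, adjusted p = 0.784). Its A to B and C log2 ratio was -0.44 in DMSO and -0.51 in ICRF-193. None of the 13 protein genes of the mitochondrial genome is in the deposited table.

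Of 16 heat shock genes 2 rose, Hspa1a from 51.2 ± 8.58 to 193.2 ± 42.5 normalised reads and Hspa1b from 159.9 ± 47.1 to 381 ± 85.3 (mean ± SD, n = 3), the same adjusted over the list alone. These 2 genes are near-identical copies, so their reads cannot be assigned with certainty. The heat shock median was -0.11 and the mean 0.10, and the median was 0.05 when libraries were scaled by total reads (permutation test, adjusted p = 0.707). Of 17 housekeeping genes 1 rose, B2m, the light chain of class I antigen presentation, from 1215 ± 60.7 to 2304 ± 363 (mean ± SD, n = 3), with 1 higher and 1 lower adjusted over the list alone. The housekeeping median was -0.32, with an A to B and C log2 ratio of -0.21 in DMSO and -0.24 in ICRF-193 (permutation test, adjusted p = 0.0885), and passed on the recovered reads (-0.36), also without DMSO-A (-0.51), ICRF-193-B (-0.39) or ICRF-193-C (-0.47). Among the 39 lists with reads, 10 medians lay above and 9 below those of random lists of similar level at an adjusted p under 0.05. With a correlation estimated in camera no list passed. The lowest adjusted p was 0.0961, and 0.269 with the split term. With the preset correlation of 0.01 and in fry some lists passed. Adjusted p was 7.85e-17 in camera with the preset and 6.35e-04 in fry for p53 targets. It was 1.61e-05 and 0.00914 for the unfolded protein and integrated stress response, and 8.90e-05 and 6.50e-04 for G2 and mitosis. For ribosomal proteins it was 0.00166 and 0.334. The list results thus depend on the correlation assumed between members.

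**Figure D4:**
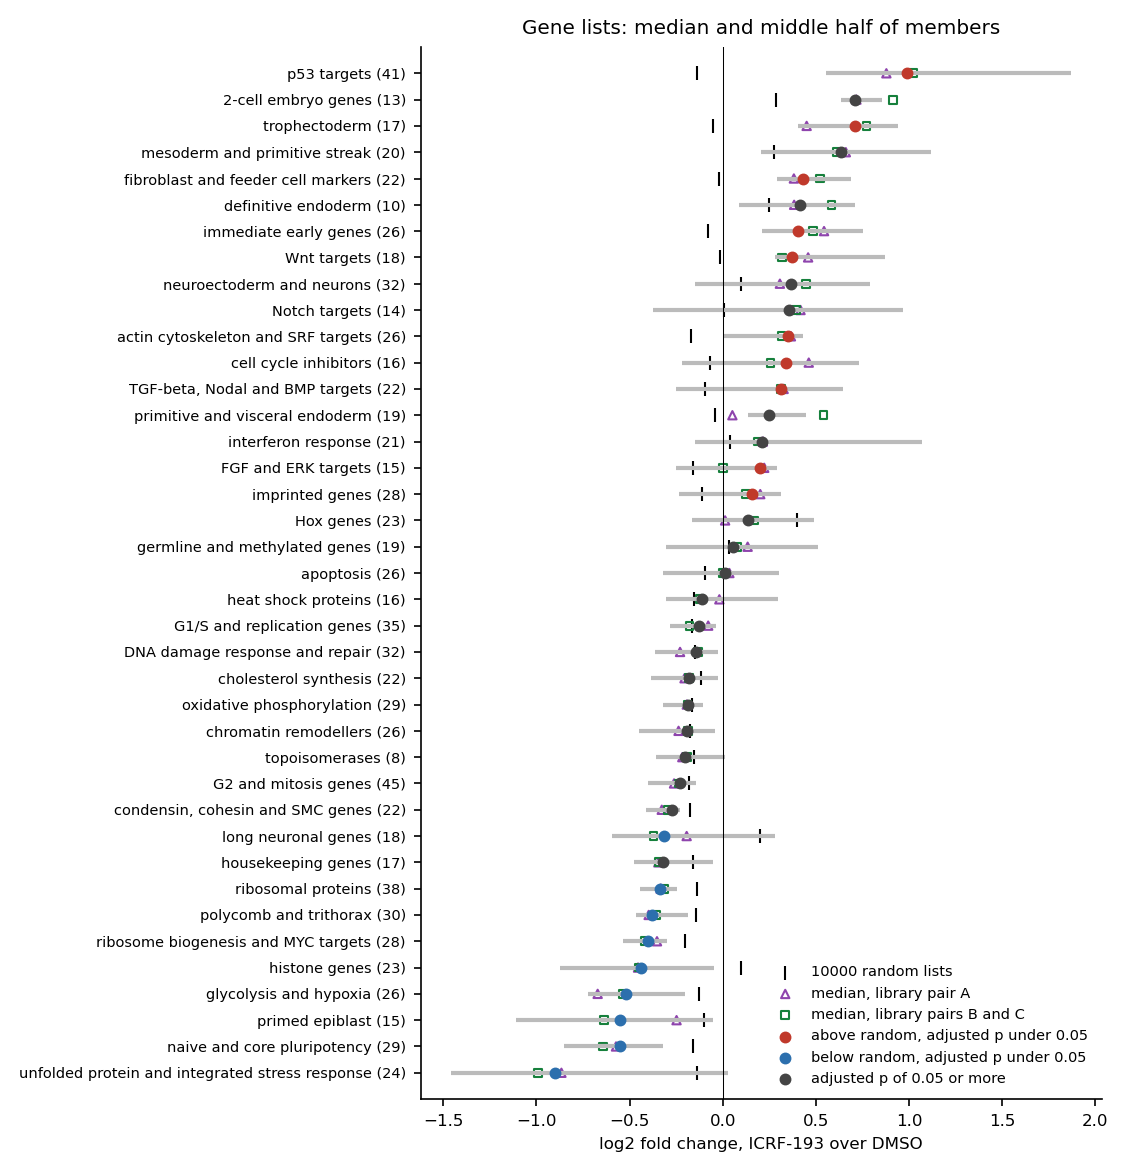
Median log2 fold change of each fixed gene list (x axis), with the medians of pair A and of pairs B and C beside it. The p53 targets sit at 0.99 and the unfolded protein and integrated stress response at -0.90, on the same side of 0 in pair A and in pairs B and C.

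Long genes were considered because topoisomerase inhibitors are known to act on them. Of 28 long neuronal genes 1 rose, Nrg1, a ligand of ERBB receptors, from 182 ± 13.0 to 330.3 ± 20.9 normalised reads (mean ± SD, n = 3), also 1 adjusted over the list alone. Their median was -0.32, -0.19 in pair A and -0.37 in pairs B and C (permutation test, adjusted p = 0.00364; adjusted p = 0.532 with an estimated correlation). Across 17438 genes the deposited log2 fold change had a Spearman's rho with gene span of 0.0466, 0.036 in pair A and 0.0624 in pairs B and C. With exonic length rho was 0.0333, and with the mean level of 17705 genes it was -0.359, so that genes of low level had the higher fold changes. Among the 14746 genes at a mean level of 10 or more, the median log2 fold change went from -0.12 in genes under 5 kb to 0.13 over 400 kb; in pair A the median of the longest genes was 0.00. Genes next to each other on a chromosome had similar log2 fold changes, with a rho of 0.144 over 17417 neighbour pairs against -0.0214 to 0.025 when gene order was permuted (permutation test, p = 0.000999, the smallest that 1000 permutations can give). These are relations across genes, which are not independent replicates, and 98.42% of the genes with reads had a length by symbol in the newer annotation.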

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

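All tests on recovered reads, scaling by total reads, the split term, the pair term and the fit without both libraries A were chosen after the deposited values were seen; the thresholds, level minimums and pseudocounts were planned. Limma-voom, upper quartile scaling and left-out libraries were planned for deposited counts, and were moved to the recovered reads. Higher genes (1120) became 745 at an adjusted p under 0.01, 703 at a level of 100 or more, 348 with Bonferroni and 4056 with the split term; lower genes (237) became 373 at 0.1, 109 at 0.01, 92 at a log2 fold change of 1 or more, 34 with Bonferroni, 892 with limma-voom and 4895 with the split term. In limma-voom (1461 higher, 892 lower) they became 3761 and 4322 without both libraries A, 4155 and 5079 with the pair term, 587 lower with upper quartile and 407 lower with total read scaling, and 476 to 1719 higher and 109 to 1382 lower when 1 library was left out; with the split term 3063 were lower after total read scaling. When 1 library was left out of the fit with the split term, 3333 to 3760 were higher and 4135 to 4540 lower. Stricter thresholds call fewer genes by construction. For the other settings the cause was not tested. Topoisomerase genes (0) became 2 with limma-voom, also without a filter and with either other scaling, 6 without both libraries A, 7 with the pair term or split term, and 0 to 3 with 1 library left out. The rank correlation of log2 fold change became 0.0854 with gene span and 0.0967 with exonic length at a level of 100 or more, and with mean level -0.331 at 10 or more, -0.221 at 100 or more and -0.336 with the split term. Lists above random ones (10) stayed between 7 and 13 and those below (9) between 8 and 11; neighbour rho lay between 0.0961 and 0.144, and at 0.0730 for neighbours over 10 kb apart that share no 3 letters. The median of FGF and ERK targets (0.20) turned to -0.231 without ICRF-193-A and to -0.0004 without both libraries A. Without ICRF-193-A, that of TGF-beta, Nodal and BMP targets (0.31) turned to -0.0131 and that of Hox genes (0.14) to -0.121. The last 2 lists were higher in libraries A, and this fit keeps a library A in DMSO only, which lowers their fold change. How much of the turn this explains was not tested, nor was the cause for FGF and ERK targets. With the split term the medians of the 3 lists were 0.18, 0.31 and 0.26. The share of higher genes among the calls was 82.5% in the deposited test, 62.1% in limma-voom, and with the split term 45.3%, or 54.5% and 63.6% after upper quartile and total read scaling. No other list median or named gene that passed changed sign. The next counts leave out the fits without 1 library but include the fit without both libraries A. Of list medians 364 were the same, 18 newly passed, 7 no longer did and 1 reversed. The reversal came only without both libraries A. Of named genes 656 were the same, 80 newly passed in a limma-voom fit and 14 no longer did. In the group fit, leaving out 1 library ended 35 calls of named genes without DMSO-B, 35 without ICRF-193-B and 32 without ICRF-193-C. It ended 27 without DMSO-C, 7 without ICRF-193-A and 5 without DMSO-A. Recentring moves every gene alike and so nothing in the list tests. By replicate number no paired analysis was possible because the deposited columns carry none; the pair term above, which was run instead, rests on size factors, and deviations from the group mean correlated at 0.902, 0.735 and 0.822 between libraries of the same letter, against 0.718 for DMSO-B with ICRF-193-C and 0.613 for DMSO-C with ICRF-193-B. The planned edgeR and DESeq2 fits and TMM scaling were not run, since the files give means and not counts per replicate, and the recovered reads, being inferred, were tested with limma-voom only. Depth limits genes such as Neurog2, Irf7 and Usp18, with few DMSO reads.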

Other observations

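The gene lists in the first 2 paragraphs and, apart from that of GC content, all tests of explanations below were chosen only after the result was seen. The medians of these lists are given without a test, since they hold members whose values had been seen. Genes of stratified epithelium, the layered lining of skin and mouth, gave 20 higher genes of 36, with the other 16 not passing. Zfp750, a regulator of skin differentiation, rose from 155 ± 27.4 to 1156 ± 55.2 normalised reads, Itgb4, a hemidesmosome integrin, from 496 ± 99.5 to 2047 ± 80.7, the cadherin gene Dsc3 from 12.9 ± 0.975 to 98.3 ± 22.7, and Sbsn from 91.7 ± 7.52 to 635 ± 176 (mean ± SD, n = 3). Trp63, the master regulator of this tissue, was at 1.85 ± 0.749 to 3.19 ± 1.22 (mean ± SD, n = 3) and did not pass. The list's median log2 fold change was 1.68, 1.62 in pair A and 1.69 in pairs B and C. Of 19 Wnt ligands 10 rose and 9 did not pass, with a median of 1.51, 1.03 in pair A and 1.85 in pairs B and C. Beside Wnt3, Wnt3a, Wnt8a and Wnt8b these were Wnt4, Wnt6, Wnt9a, Wnt9b, Wnt10a and Wnt10b, of which Wnt4 and Wnt10b did not pass in limma-voom (adjusted p = 0.0521 and 0.0567); Wnt6 rose from 38.5 ± 18.4 to 214 ± 17.0 and Wnt9a from 286 ± 113 to 816 ± 61.2 (mean ± SD, n = 3). Of 32 genes of the motile cilium 8 rose and 1, Rsph1, fell. Foxj1, the master regulator of motile cilia, rose from 102 ± 23.3 to 429 ± 90.5 and Ttll6, a tubulin ligase, from 161 ± 43.8 to 1229 ± 321 (mean ± SD, n = 3), while the list's median was 0.33.

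Of 20 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 11 fell and 9 did not pass. Aars fell from 31351 ± 2791 to 13269 ± 806 and Yars from 9941 ± 604 to 4219.5 ± 160.4 normalised reads (mean ± SD, n = 3), and the median was -0.75, -0.81 in pair A and -0.72 in pairs B and C. Of the 17 mitochondrial synthetases the authors' DESeq test called 0, with 2 lower at an unadjusted p under 0.05; limma-voom called 2 lower, and with the split term 1 higher and 10 lower, with a median of -0.32. Of 23 amino acid transporters 6 fell, 1 rose and 16 did not pass. Slc1a4 fell from 2425 ± 176 to 804 ± 84.7, Slc6a9 from 612 ± 88.1 to 198 ± 37.4 and Slc7a5 from 17482 ± 1933 to 9631 ± 1037, while Slc1a1 rose from 80.8 ± 18.0 to 179 ± 32.4 (mean ± SD, n = 3). The transporter median was -0.15, and 0.00 with total read scaling.

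Libraries A stood apart from B and C in both groups. GC content as the cause is argued against by a partial rank correlation of -0.0661 in DMSO and -0.118 in ICRF-193 after exonic length and level. Fibroblasts or feeder cells as the whole cause are argued against by the 2-cell embryo genes, which fibroblasts do not bring and whose A to B and C log2 ratio had a length-corrected median of 2.83. A bias of library preparation with gene length is a candidate explanation for part of it, since the ratio had a rho with exonic length of at least 0.592 in both groups, against 0.0957 and 0.274 between libraries B and C. After correction for length, medians of the ratio remained at 1.74 in DMSO and 1.135 in ICRF-193 for primitive and visceral endoderm. They were 1.40 and 1.10 for Hox genes, 0.19 and 0.29 for naive and core pluripotency, and -0.66 and -0.48 for primed epiblast. A different state of the ES cells in libraries A was not tested. The culture was without feeder cells, which would remove these as a source. For the fibroblast genes, with a length-corrected median of 1.01, remaining fibroblasts and a change of the ES cells cannot be told apart, since no library has a known share of either. Members differ: Col1a1 and Col3a1 were over 10 times as high in DMSO-A as in DMSO-B or DMSO-C, but Thy1 was at 185 against 281 and 311 normalised reads. Length-corrected, 18 of 21 members lay above 0 in DMSO and 19 of 21 in ICRF-193.

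Of 24 genes of the unfolded protein and integrated stress response 14 fell (list, adjusted p = 0.333 with an estimated correlation). The scaling is argued against by a list median of at most -0.80 under the other scalings, and the split of the libraries by one of at most -0.86 in each of the 3 library pairs. Lower activity of the transcription factor ATF4, whose known targets include the cytosolic synthetases, cannot be told apart from other causes. Their median minus that of the mitochondrial ones was -0.43, but the family was chosen after its fall was seen, so the difference tests nothing. A different density or medium of the dishes cannot be told apart from the drug, since the labels give the density at seeding but not at harvest, and 5 of 26 glycolysis and hypoxia genes fell too, with 21 not passing (median -0.52; adjusted p = 0.0961 with an estimated correlation).

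Neighbouring genes had correlated log2 fold changes. Paralogs and overlapping genes as the whole cause are argued against by a rho of 0.0730 over 7686 neighbour pairs more than 10 kb apart that share no 3 letters of their symbols, beyond the -0.0333 to 0.0304 of permuted orders. A shared expression level is argued against by a rho of 0.138 after ranking among genes of similar level. The ratio of libraries A to B and C, which holds no treatment, gave a rho of 0.139 (0.117 length-corrected) where the log2 fold change gave 0.135, so neighbours may vary together in any contrast of these libraries. No biological explanation particular to topoisomerase II was tested.

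The 6 libraries make 10 splits into 3 and 3, and 1 of the 10, the real one, gave as many genes in limma-voom (2353) as the treatment, with at most 0 in the others; a share under 0.05 cannot be reached with 10 splits. With the split term 6 splits could be used and 1 of the 6, the real one, gave 8951 genes, with at most 0 in the others; these splits too are too few for a share under 0.05.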
